A study of Mus musculus with 8 samples.

How the data were processed

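RNA from mouse liver was sequenced in 8 samples, 4 labelled EcSTH and 4 labelled GFP, each group numbered 1 to 4 in the labels. RNA was purified with an RNeasy mini plus kit and libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols, which do not say whether the libraries kept the strand. Per the submitters' processing notes, reads were processed with Salmon 1.5.1, which estimates transcript abundance without full alignment, and with DESeq2 1.30.1, using the mouse build mm10. The annotation release and the way transcripts were summed per gene are not given in the sources used here.

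The deposited values are normalized counts, a signal that is never negative, 1 column per sample and 1 value per gene symbol, per the file headers. In each column the values were whole multiples of that column's smallest value above 0, so the authors' read estimates could be recovered as whole reads: 100% of the values in each sample were whole within 0.01 read. The table held 27770 gene symbols, of which 10226 were at 0 in all 8 samples. Recovered totals lay between 16769278 and 20014661 reads per sample (EcSTH 18.0 ± 1.35 M, GFP 18.4 ± 1.20 M, mean ± SD, n = 4). A value is an estimate shared out among transcripts: of 10394 genes with a mean of at least 50, 78 were listed at 0 in at least 1 sample, among them widely expressed genes such as Srrm2 and Prkaa1, so a listed 0 can be a failed estimate. For named genes with such zeros the value of each library is given. Limits taken from a count of 0 cover counting error only.

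Genes with a mean of at least 10 over the 8 samples were tested (12500 genes). Log2(value + 1) was fitted with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, with the group as the only term, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. Log2 fold changes are EcSTH minus GFP on the log2(value + 1) scale, which understates the change of low genes, and folds are their antilogs. Because the values are normalized, the count models, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, were run only as alternatives on the recovered reads. The steps were tested on simulated counts for the same 12500 genes and depths, with 200 genes changed: limma recovered 41.8% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 89.4% of those changed 4-fold, and 5.11% of its calls fell on unchanged genes. DESeq2 recovered 73.1% of those changed 2-fold, and 20.8% of its calls fell on unchanged genes. A further list of 20 genes was shifted together and counted as changed. Each gene was drawn on its own, without differences shared by many genes within a sample, so these rates may not hold for the real samples.

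The following choices were made before the data were examined. Gene lists numbered 46 (925 entries, 8 matched through RefSeq synonyms and 2 not matched) and covered pathways and markers of other cell types. Each list was tested with camera in limma at its preset correlation of 0.01, two-sided and adjusted over the 46 lists, and again with a correlation estimated from these samples. Counts of changed members are given over all genes and adjusted over the list alone. The genes named were the 10 with the largest rise and the 10 with the largest fall among genes past the threshold, with no overlap between the groups, a mean of at least 50 in the higher group and a full gene name, then 12 genes fixed by name, then for each list the up to 4 members with the smallest adjusted p and any that went against their list. Of the genes that meet this rule, 2 are not reported here. The exceptions, Acly, Pnpla3, Mki67, Cdkn1a, Tgtp2, Gsta2, Cyp4a32, Vsig4, Timd4, Amy2a5, Pnlip, Alb and Saa1, were chosen after their values were seen.

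Coordinates and gene types come from the GENCODE M21 annotation of the same build, which held 26264 of the 27770 symbols. It may not be the release behind the deposited values. Of the 127 named genes, 34 share exon sequence with another annotated gene, mostly on the opposite strand, and reads of such pairs may have been split between them (Elovl6, Me1, Pklr, Mlxipl, Txnip, Mcm7 and Lss are examples). Reads of near-identical families (Gsta1 and Gsta2, Tgtp1 and Tgtp2, the Cyp4a, Cyp2c and Serpina1 genes) can also be divided wrongly, so values of single members are uncertain. Sums over such families were added after the values had been seen. Pairs of replicates within a group differed by far more than sampling noise (chi-square over degrees of freedom of at least 16.9), so each library was counted as a sample. No label names a batch.

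Alternatives changed the pseudocount, the filter on low values, the scaling (median ratio, TMM-type and quantile), the variance model, the sample weights and the tool, added the replicate number as a block, asked for a change of over 1.2-fold (treat), or left out each library in turn. The fry test in limma was a further alternative for the lists. Covariates numbered 3 and were added after the data had been seen: the share of mitochondrial mRNA, the cell cycle level and the level of pancreatic acinar markers.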

Results

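Liver RNA was compared between mice given EcSTH and mice given GFP. EcSTH is the soluble transhydrogenase of Escherichia coli, an enzyme that passes reducing equivalents between the NAD and NADP pools, and was delivered by an adenovirus injected behind the eye. Livers were collected 4 days later. GFP, green fluorescent protein, served as the control. Each group had 4 samples, sequenced to between 16769278 and 20014661 recovered reads. The labels do not say that the samples of a group came from separate animals, so the p-values measure the spread between these samples. The question of the series is how reductive stress, an excess of reducing equivalents, acts on ChREBP, the carbohydrate-responsive transcription factor encoded by Mlxipl.

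Lists of ChREBP targets, cell cycle genes and interferon-stimulated genes were higher in EcSTH livers, and lists of amino acid breakdown, cholesterol synthesis and drug metabolism were lower, by camera at its preset correlation. In all, 26 of 46 lists passed that test and 0 passed with an estimated correlation (lowest adjusted p = 0.321). Among the lists that passed, the mean levels of samples overlapped between the groups for glycolysis, fatty acid oxidation, oxidative phosphorylation, bile acid, steroid and growth hormone lists. They also overlapped for heat shock, antigen presentation, unfolded protein response, endothelial, stellate and erythroid lists. Of 12500 genes tested, 852 differed (limma, adjusted p under 0.05), 453 higher and 399 lower in EcSTH. Changes of at least 2-fold were found in 218 genes, 193 higher and 25 lower. In 832 of the 852 no EcSTH sample overlapped a GFP sample. Over all tested genes 15.7% had such separation, where chance gives 2.86%. The first principal component, with 31.1% of the variance, placed the EcSTH samples on the other side from the GFP samples. The GFP samples were uneven on it, at 46.6 in GFP sample 1, a little less in GFP sample 2, and 8.39 and 14.8 in GFP samples 3 and 4. GFP sample 3 thus lay nearer to EcSTH sample 4 (-15.7) than to GFP samples 1 and 2, so this component also holds differences within the GFP group. The count fell to 364 genes without EcSTH sample 1, to 233 without EcSTH sample 2, to 193 without EcSTH sample 4, to 285 without GFP sample 1 and to 247 without GFP sample 2. It was 773 without EcSTH sample 3, 909 without GFP sample 3 and 813 without GFP sample 4. With the cell cycle level as a covariate, limma called 0 genes, and 871 had an unadjusted p under 0.05. Of the 114 named genes past the threshold, 44 passed it in each of the 8 fits without a library, 18 lost it in 1 to 3 fits and 52 in 4 or more.

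Targets of ChREBP rose as a group. Of the 24 listed targets, 10 rose and none fell (12 adjusted over the list alone), with a mean log2 change of 0.69 (camera adjusted p = 8.55e-09; adjusted p = 0.321 with an estimated correlation). Elovl6, which elongates fatty acids, rose 2.91-fold from 1351 ± 100.4 normalized counts in GFP to 4037 ± 1051 in EcSTH (SD, n = 4; log2 1.54, SE 0.17, limma adjusted p = 0.00545). Me1, the cytosolic malic enzyme that makes NADPH, rose 2.17-fold (4034 ± 429 to 8819 ± 1639.7, adjusted p = 0.00637). Dak, the triokinase gene now called Tkfc, rose 1.99-fold (adjusted p = 0.0107). Thrsp (2.35-fold), Acaca, the acetyl-CoA carboxylase gene (2.25-fold), and Acly, the ATP citrate lyase gene (1.95-fold), also rose. These 6 genes passed the threshold in every fit without a library. Pklr, the liver pyruvate kinase gene, rose 1.81-fold (4807 ± 629.7 to 8873 ± 2325, adjusted p = 0.0234). Fgf21, a liver hormone gene, rose 3.86-fold (22.8 ± 12.1 to 85.3 ± 28.9, adjusted p = 0.0297). Pnpla3, a lipase-family gene at low level, rose by 2.32 on the log2 scale and was tested in 6 of the 8 fits. Calls were lost, with the range of log2 over the fits without a sample in brackets, for Pklr (0.72 to 0.97) without EcSTH 2 or GFP 1 or 2, for Fgf21 (1.59 to 2.24) without EcSTH 2, 3 or 4 or GFP 1 or 2, and for Pnpla3 (2.00 to 2.58) without EcSTH 1 or 4 or any GFP sample. The number of targets past the threshold was 10, 7, 8 and 8 without EcSTH samples 1 to 4 in turn and 7, 7, 9 and 9 without GFP samples 1 to 4.

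Several well-known genes of sugar response did not pass. Mlxipl itself was at 5046 ± 694 in EcSTH and 5190.2 ± 639 in GFP (log2 -0.04, SE 0.11, adjusted p = 0.861). Txnip, a classical ChREBP target, was at 2057 ± 743 and 2088 ± 532 (adjusted p = 0.927). G6pc, the catalytic subunit of glucose-6-phosphatase, was at 12201 ± 3246 and 7074 ± 3828 (log2 0.97, SE 0.43, adjusted p = 0.202), and its GFP samples spread widely. Khk, the ketohexokinase gene, had a log2 change of 0.13 (SE 0.11, adjusted p = 0.544). Fasn, the fatty acid synthase gene, had 0.78 (SE 0.32, adjusted p = 0.18), and the desaturase gene Scd1 had 0.01 (SE 0.22, adjusted p = 0.985). Gckr, the glucokinase regulator named in the series title, was listed at 0, 16.6, 19.6 and 59.1 in the EcSTH libraries and at 20.7, 0, 7.22 and 5.01 in the GFP libraries (log2 1.09, SE 1.29, adjusted p = 0.669). Since a listed 0 can be a failed estimate and the error is wide, these values do not show whether Gckr changed.

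**Figure D1:**
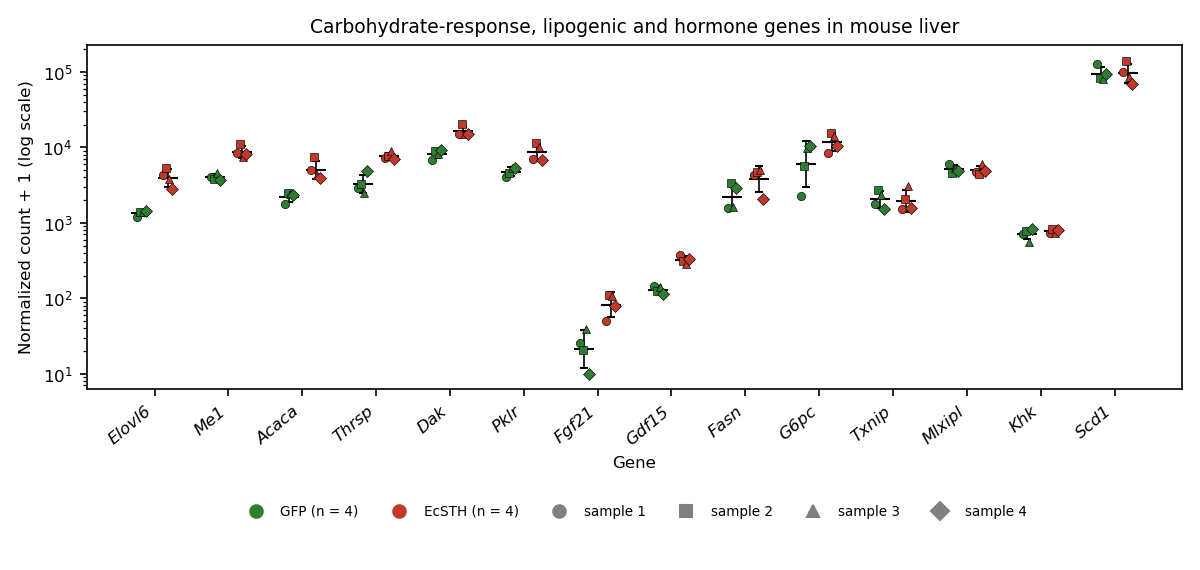
Normalized counts plus 1 (log axis) of 14 metabolic and hormone genes in the 8 liver samples (green GFP, red EcSTH, marker shape by sample number, black bars mean and SD of log2 values, n = 4 per group). The groups were apart for Elovl6, Me1, Acaca, Dak, Pklr, Fgf21, Gdf15 and Thrsp, and overlapped for Fasn, G6pc, Txnip, Mlxipl, Khk and Scd1.

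Locations in mm10 of the main protein-coding genes were as follows. Elovl6 lies on chromosome 3 from 129532355 to 129638495, and Me1 on chromosome 9 from 86581371 to 86695953. Acaca lies on chromosome 11 from 84129672 to 84401651, and Thrsp on chromosome 7 from 97412938 to 97417730. Pklr lies on chromosome 3 from 89136142 to 89146784, and Fgf21 on chromosome 7 from 45613886 to 45615490. Mlxipl lies on chromosome 5 from 135089890 to 135138382, and Gdf15 on chromosome 8 from 70629393 to 70632456. Aurka lies on chromosome 2 from 172356190 to 172370535, and Cxcl9 on chromosome 5 from 92321347 to 92328079. Gsta1 lies on chromosome 9 from 78230656 to 78242684, and Clec4f on chromosome 6 from 83644542 to 83656187. Cyp4a14 lies on chromosome 4 from 115486200 to 115496142, and Lss on chromosome 10 from 76531588 to 76557138. The values count reads over the exons of each gene's transcripts.

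Lists built on lipid and sugar pathways overlapped with these genes and gave mixed results. In de novo lipogenesis, 6 of 20 genes rose (the ChREBP targets Elovl6, Me1, Thrsp, Acaca, Acly and Pnpla3) and Acss2, which makes acetyl-CoA from acetate, fell 1.47-fold (9 adjusted over the list alone; camera adjusted p = 0.086, adjusted p = 0.526 with an estimated correlation). In glycolysis and fructolysis, 5 of 21 rose and none fell (camera adjusted p = 0.0244, adjusted p = 0.412 with an estimated correlation), including Dak, Pklr and Gpi1, the glucose-6-phosphate isomerase gene (1.68-fold, adjusted p = 0.0122). Adjusted over the list alone 6 passed, 5 higher and 1 lower. The number of risen glycolytic genes was 4, 3, 5 and 4 without EcSTH samples 1 to 4 in turn and 3, 3, 5 and 5 without GFP samples 1 to 4, and the list missed the threshold without GFP 1 (adjusted p = 0.0755) or GFP 3 (0.0623). In gluconeogenesis, Pcx, the pyruvate carboxylase gene, rose 1.60-fold, while Gpt, the alanine aminotransferase gene, fell 1.69-fold and Crtc2 fell 1.32-fold among 16 tested (7 adjusted over the list alone; camera adjusted p = 0.086, adjusted p = 0.427 with an estimated correlation). Lipoprotein and lipid droplet genes had 1 rise, Mttp (1.35-fold), and 2 falls, Apoa1 (1.53-fold) and Pnpla2 (1.25-fold), among 29 (6 adjusted over the list alone; camera adjusted p = 0.882, adjusted p = 0.898 with an estimated correlation). Leaving out samples ended the calls of Acss2 (-0.66 to -0.49), Mttp (0.35 to 0.51) and Pnpla2 (-0.35 to -0.26) without EcSTH 1, 2 or 4 or GFP 1, 2 or 4, Apoa1 (-0.69 to -0.54) and Crtc2 (-0.43 to -0.34) without EcSTH 1, 2 or 4 or GFP 1 or 2, and Pcx (0.60 to 0.79) without EcSTH 2 or 4 or GFP 2. The same held for Pklr (0.72 to 0.97) without EcSTH 2 or GFP 1 or 2, and for Pnpla3 (2.00 to 2.58) without EcSTH 1 or 4 or any GFP sample. Lists passed that otherwise had not, de novo lipogenesis without EcSTH 4 (adjusted p = 0.00904) and gluconeogenesis without EcSTH 4 (0.0424) or GFP 1 (0.0281). By direction, the de novo lipogenesis genes passing over the list alone were 6 higher and 3 lower, with a list median of 0.02 and a mean of 0.39. Gluconeogenesis had 2 higher and 5 lower, and the lipoprotein and lipid droplet list 3 higher and 3 lower.

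Genes of the pyridine nucleotide pools moved in both directions. In the pentose phosphate and NADPH list, 3 of 17 genes rose, Me1, Pgd (1.91-fold, 769.8 ± 84.6 to 1475 ± 176, adjusted p = 0.00656) and Rpia (1.92-fold), while the folate enzyme gene Aldh1l1 fell 1.52-fold (7 adjusted over the list alone; camera adjusted p = 0.882, adjusted p = 0.932 with an estimated correlation). Its median was -0.03, its mean 0.14 and the direction of its test upward. Among 17 genes of NADH shuttles and lactate, Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase gene, rose 1.95-fold (774 ± 106 to 1539 ± 409, adjusted p = 0.0158). The lactate transporter gene Slc16a1 rose 1.42-fold, and the glutamate carrier gene Slc25a22 fell 1.25-fold (7 adjusted over the list alone; camera adjusted p = 0.196, adjusted p = 0.526 with an estimated correlation). In NAD synthesis and use, Nampt rose 1.34-fold and Tdo2 fell 1.33-fold among 18 (3 adjusted over the list alone; camera adjusted p = 0.263, adjusted p = 0.526 with an estimated correlation). Nnt, the mitochondrial transhydrogenase gene, was at 617 ± 211 in EcSTH and 839.8 ± 214 in GFP (adjusted p = 0.279). The TCA cycle list had 2 rises, Pdhb (1.56-fold, adjusted p = 0.0107) and Pcx, and 2 falls, Sdhc (1.19-fold) and Sdhb (1.24-fold), among 22 (8 adjusted over the list alone; camera adjusted p = 0.169, adjusted p = 0.526 with an estimated correlation). Limma called none of 29 nuclear oxidative phosphorylation genes alone (8 at an unadjusted p under 0.05, 0 with edgeR and 4 with DESeq2; mean log2 -0.18, camera adjusted p = 0.00404; adjusted p = 0.526 with an estimated correlation), and none of 13 mitochondrial mRNAs (0 at an unadjusted p under 0.05, 0 with edgeR and 0 with DESeq2; camera adjusted p = 0.768, adjusted p = 0.932 with an estimated correlation, and past the threshold without EcSTH 3, adjusted p = 0.0379). The mean level of the nuclear list, centred over the samples, overlapped between the groups. It was -0.21, -0.30, 0.12 and 0.03 in EcSTH samples 1 to 4 and 0.005, 0.11, 0.01 and 0.24 in GFP. The share of mitochondrial mRNA varied within both groups, from 3.69% to 9.34% in EcSTH and from 3.96% to 7.51% in GFP. By direction, the genes passing over the list alone were 4 higher and 3 lower for NADPH supply and 2 higher and 5 lower for NADH shuttles. NAD synthesis and use had 1 higher and 2 lower, and the TCA cycle 2 higher and 6 lower. Pgd, Gpd2 and Pdhb passed in all 8 fits without a library. Not past the threshold in some fits were Rpia (0.82 to 1.04) without EcSTH 2 or 4, Aldh1l1 (-0.71 to -0.50) without EcSTH 2 or 4 or GFP 1 or 2, and Nampt (0.36 to 0.48) without EcSTH 1 or 4 or GFP 1 or 2. Calls were also lost for Slc25a22 (-0.36 to -0.29) without EcSTH 1, 2 or 4 or GFP 2 or 4, for Slc16a1 (0.43 to 0.59) and Sdhb (-0.37 to -0.27) without EcSTH 1, 2 or 4 or GFP 1, 2 or 4, and for Tdo2 (-0.46 to -0.34) and Sdhc (-0.30 to -0.23) without EcSTH 1, 2 or 4 or any GFP sample. The threshold was missed for Pcx (0.60 to 0.79) without EcSTH 2 or 4 or GFP 2.

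Amino acid and cholesterol genes fell. Of 24 genes of the urea cycle and amino acid breakdown, 11 fell and none rose (16 adjusted over the list alone; camera adjusted p = 3.43e-12; adjusted p = 0.321 with an estimated correlation). Prodh, the proline dehydrogenase gene, fell 1.75-fold (3105 ± 433 to 1768 ± 158, adjusted p = 0.0107). Hpd of tyrosine breakdown fell 1.64-fold to 18346 ± 1599.7, Agxt fell 1.69-fold and Uroc1 of histidine breakdown fell 1.45-fold. All 4 passed in every fit without a library. In cholesterol synthesis 5 of 24 genes fell and none rose (21 adjusted over the list alone; mean log2 -0.53, camera adjusted p = 2.77e-11; adjusted p = 0.325 with an estimated correlation). The mean level of the cholesterol list, centred over the samples, was 0.02, -0.64, -0.05 and -0.40 in EcSTH samples 1 to 4. In GFP samples 1 to 4 it was 0.14, 0.52, 0.17 and 0.23. Lss, the lanosterol synthase gene, fell 2.17-fold (1173 ± 155 to 557 ± 176, adjusted p = 0.0175), with smaller falls of Tm7sf2 (1.42-fold), Stard4 and Sc5d (1.41-fold each). The threshold was missed in fits for Lss (-1.28 to -0.95) without EcSTH 4 or GFP 2, for Tm7sf2 (-0.57 to -0.45) without EcSTH 4, and for Stard4 (-0.56 to -0.40) without EcSTH 2 or 4 or GFP 1 or 2. Calls were also lost for Sc5d (-0.58 to -0.41) without EcSTH 2, 3 or 4 or GFP 1 or 2. The number of fallen cholesterol genes was 5, 2, 7 and 0 without EcSTH samples 1 to 4 in turn and 2, 1, 5 and 5 without GFP samples 1 to 4, and of amino acid genes 10, 6, 10 and 5 without EcSTH samples 1 to 4 in turn and 8, 8, 12 and 9 without GFP samples 1 to 4.

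Among listed fatty acid oxidation genes the largest falls were in the Cyp4a family, which hydroxylates fatty acids at the omega end. Cyp4a14 fell 4.20-fold (2255 ± 871 to 555 ± 272, adjusted p = 0.0168), Cyp4a10 fell 2.44-fold (6227 ± 1777 to 2556 ± 758) and Cyp4a31 fell 2.21-fold (325 ± 88.2 to 145 ± 29.8). Summed with Cyp4a32, they fell 2.62-fold (adjusted p = 0.0145). Of the 30 listed oxidation and ketogenesis genes, 6 fell, Cyp4a10 and Cyp4a14 among them, and Fgf21 rose (11 adjusted over the list alone; camera adjusted p = 0.000177; adjusted p = 0.412 with an estimated correlation). Acaa2 of the thiolase step fell 1.34-fold. Cpt1a, which admits fatty acids to mitochondria, was at 9131 ± 299 and 9774 ± 680.4 (log2 -0.10, SE 0.07, adjusted p = 0.456). In fits without a sample, the calls of Cyp4a14 (-2.36 to -1.75) and Cyp4a10 (-1.47 to -1.12) ended without EcSTH 2 or GFP 2. Acaa2 (-0.48 to -0.38) lost its call without EcSTH 1, 2 or 4 or GFP 1 or 2. Fgf21 (1.59 to 2.24) lost its call without EcSTH 2, 3 or 4 or GFP 1 or 2. The number of fallen oxidation genes was 2, 0, 5 and 2 without EcSTH samples 1 to 4 in turn and 2, 0, 3 and 7 without GFP samples 1 to 4.

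Hepatocyte functions were lower as well. Albumin took 4.54% ± 0.370 of reads in EcSTH and 6.03% ± 0.344 in GFP. Of 19 hepatocyte identity genes 6 fell (13 adjusted over the list alone; camera adjusted p = 1.5e-07; adjusted p = 0.321 with an estimated correlation), among them Serpina1d (1.39-fold), Apoa2 (1.46-fold) and Apoh (1.26-fold). Of 19 xenobiotic genes 6 fell (8 adjusted over the list alone; camera adjusted p = 6.38e-07; adjusted p = 0.321 with an estimated correlation), with Cyp1a2 down 1.65-fold (12246 ± 1182 to 7422 ± 882, adjusted p = 0.0107), Cyp2c54 1.78-fold, Cyp2c37 1.73-fold and Cyp2c50 1.63-fold (1.68-fold for the sum of these 3, adjusted p = 0.0120). Genes marking both ends of the liver lobule fell, 6 of 17 pericentral genes (camera adjusted p = 6.38e-07) and 5 of 17 periportal genes (camera adjusted p = 0.0016), each with adjusted p = 0.321 with an estimated correlation. Adjusted over the list alone, 10 pericentral genes passed, all lower, and 10 periportal genes, 8 lower and 2 higher. The pericentral genes included Rnf43, a regulator of Wnt signalling (1.68-fold, adjusted p = 0.0107), Cyp2e1 (1.63-fold) and Gulo (1.52-fold), and the periportal genes Hal (1.70-fold), Gls2 (1.41-fold) and Ass1 (1.56-fold). Bile acid genes fell in 3 of 20 cases (mean log2 -0.028, camera adjusted p = 0.0244, adjusted p = 0.355 with an estimated correlation), Cyp27a1 (1.49-fold), Slc27a5 (1.52-fold) and Slco1a1 (1.33-fold). Adjusted over the list alone 7 passed, 6 lower and 1 higher. Steroid and sex-biased genes fell in 4 of 16 (camera adjusted p = 0.024, adjusted p = 0.412 with an estimated correlation), Elovl3 (1.52-fold), Cyp2d9 (1.33-fold), Cyp4a12b (1.42-fold) and Slco1a1. Adjusted over the list alone 5 passed, 4 lower and 1 higher. Igfbp2 fell 2.04-fold (12000.1 ± 1448 to 5993 ± 1424, adjusted p = 0.0122), with Igfbp3 and Igfbp4 (1.29-fold each), among 16 genes of the growth hormone and IGF list (3 adjusted over the list alone; camera adjusted p = 0.0244; adjusted p = 0.321 with an estimated correlation). Of 19 clock genes 4 fell (6 adjusted over the list alone; camera adjusted p = 0.00188; adjusted p = 0.321 with an estimated correlation), Dbp (1.63-fold, adjusted p = 0.0122), Bhlhe41 (2.01-fold), Tef (1.35-fold) and Usp2 (1.85-fold). Lost calls (range in brackets) were those of Tef (-0.48 to -0.36) without GFP 2, Cyp2e1 (-0.76 to -0.60), Gulo (-0.66 to -0.50), Gls2 (-0.55 to -0.44), Ass1 (-0.72 to -0.58), Slc27a5 (-0.64 to -0.50) and Bhlhe41 (-1.11 to -0.90) without EcSTH 2 or 4, and Elovl3 (-0.67 to -0.50) without EcSTH 1 or 4. Calls were also lost for Cyp2d9 (-0.45 to -0.36) without EcSTH 2 or 4 or GFP 1 or 2, and for Serpina1d (-0.52 to -0.42), Apoa2 (-0.63 to -0.48) and Slco1a1 (-0.49 to -0.37) without EcSTH 1, 2 or 4 or GFP 1 or 2. The threshold was missed for Cyp4a12b (-0.59 to -0.44) without EcSTH 2, 3 or 4 or GFP 1, 2 or 3, for Igfbp4 (-0.40 to -0.30) without any EcSTH sample or GFP 1, 2 or 4, and for Usp2 (-1.05 to -0.69) without EcSTH 1, 2 or 3 or any GFP sample. Losses were further seen for Igfbp3 (-0.42 to -0.33) and Apoh (-0.37 to -0.28) without any 1 of the 8 samples. The number of fallen hepatocyte identity genes was 1, 0, 4 and 0 without EcSTH samples 1 to 4 in turn and 0, 0, 4 and 3 without GFP samples 1 to 4. That of pericentral genes was 4, 2, 5 and 2 without EcSTH samples 1 to 4 in turn and 4, 4, 5 and 5 without GFP samples 1 to 4. That of periportal genes was 5, 2, 5 and 2 without EcSTH samples 1 to 4 in turn and 5, 5, 5 and 5 without GFP samples 1 to 4. For bile acid genes it was 2, 2, 4 and 1 without EcSTH samples 1 to 4 in turn and 2, 2, 5 and 3 without GFP samples 1 to 4, for steroid and sex-biased genes 2, 1, 4 and 0 without EcSTH samples 1 to 4 in turn and 1, 1, 3 and 4 without GFP samples 1 to 4. Growth hormone and IGF genes gave 1, 1, 2 and 1 without EcSTH samples 1 to 4 in turn and 2, 1, 2 and 1 without GFP samples 1 to 4, and clock genes 3, 2, 3 and 3 without EcSTH samples 1 to 4 in turn and 3, 2, 3 and 5 without GFP samples 1 to 4. The bile acid list missed the threshold without EcSTH 1 (adjusted p = 0.0501) or EcSTH 4 (0.0542), and its mean change was above 0 without EcSTH 4 (0.00065), without GFP 1 (0.011) and with quantile normalization (0.077). The steroid list missed it without EcSTH 2 (0.0581) or GFP 1 (0.0703), and the growth hormone list without GFP 1 (0.0755).

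Cell cycle genes had the smallest camera p of the 46 lists. Of 35 genes, 19 rose and none fell (32 adjusted over the list alone), with a mean log2 change of 1.52 (camera adjusted p = 7.27e-18; adjusted p = 0.321 with an estimated correlation). The mitotic kinase gene Aurka rose 3.41-fold (145 ± 62.0 to 466 ± 67.1, adjusted p = 0.0122) and the replication helicase gene Mcm7 1.62-fold (adjusted p = 0.0158), both past the threshold in all 8 fits without a library. The GFP samples were uneven: the list's mean level, centred over the samples, was -1.57, -1.43, -0.06 and 0.03 in GFP samples 1 to 4, against 0.96, 0.80, 0.48 and 0.79 in EcSTH. Mki67, a proliferation marker, read 143, 138, 468 and 431 in GFP and 847, 969, 647 and 834 in EcSTH (log2 1.70, adjusted p = 0.0355). Tpx2 rose 3.90-fold and Rrm2, a ribonucleotide reductase gene, 4.07-fold. The number of risen list members was 2, 2, 14 and 2 without EcSTH samples 1 to 4 in turn and 4, 3, 26 and 29 without GFP samples 1 to 4. Espl1, which encodes separase, was listed at 0, 0, 0 and 71.1 in GFP and 148, 125, 80.4 and 83.5 in EcSTH (adjusted p = 0.0389). With a sample left out, calls ended for Tpx2 (1.63 to 2.26) and Mki67 (1.41 to 2.00) without EcSTH 1, 2 or 4 or GFP 1 or 2, for Rrm2 (1.63 to 2.39) without EcSTH 1, 2 or 4 or GFP 2, and for Espl1 (4.68 to 6.73) without any EcSTH sample or GFP 1, 2 or 3.

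The p53 target list followed the same samples. Of 21 genes, 5 rose and Sesn1 fell (12 adjusted over the list alone; camera adjusted p = 4.3e-05; adjusted p = 0.321 with an estimated correlation). Its mean level was -0.60, -0.52, 0.01 and -0.07 in GFP samples 1 to 4 and between 0.13 and 0.40 in EcSTH. Cdkn1a, the cell cycle inhibitor p21, rose 4.68-fold (54.1, 89.4, 307 and 316 in GFP, 703 ± 121 in EcSTH, adjusted p = 0.034). Gdf15, a stress hormone gene, rose 2.50-fold with little spread (129 ± 14.8 to 324 ± 35.8, log2 1.32, SE 0.13, adjusted p = 0.00409) and kept its call in all 8 fits without a library. Mdm2 (1.40-fold), Aen and Bax (1.42-fold each) rose, and Sesn1 fell 1.48-fold. In fits without a sample, the call of Mdm2 (0.42 to 0.54) ended without EcSTH 2 or 4 or GFP 1 or 2. Aen (0.44 to 0.58) and Cdkn1a (1.75 to 2.59) lost theirs without EcSTH 1, 2 or 4 or GFP 1 or 2. Bax (0.43 to 0.58) and Sesn1 (-0.67 to -0.49) lost theirs without EcSTH 1, 2 or 4 or GFP 1, 2 or 4. The number of risen p53 targets was 2, 1, 5 and 1 without EcSTH samples 1 to 4 in turn and 1, 1, 9 and 6 without GFP samples 1 to 4.

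Interferon-induced genes and chemokines rose. Of 29 interferon-stimulated genes 10 rose and none fell (17 adjusted over the list alone; camera adjusted p = 9.52e-11; adjusted p = 0.321 with an estimated correlation). Cxcl9, a T cell attractant induced by interferon gamma, rose 6.80-fold (143 ± 41.1 to 1011 ± 402, adjusted p = 0.00496), Cxcl10 5.20-fold (62.5 ± 11.1 to 345 ± 139), Gbp2 4.27-fold and Irgm1 1.91-fold. The GTPase genes Gbp5 (0, 0, 6.19 and 2.00 in GFP samples 1 to 4, and 33.4, 41.6, 45.6 and 88.6 in EcSTH) and Tgtp1 (6.63-fold, 317 ± 115 to 2387 ± 1743) were among the largest rises, and the near copy Tgtp2 rose 3.83-fold (6.15-fold for the sum of both, adjusted p = 0.0120). Calls of these 7 genes held in all 8 fits without a library. Of 11 cytokine and chemokine genes 3 rose (5 adjusted over the list alone; camera adjusted p = 0.000464; adjusted p = 0.321 with an estimated correlation), the third being Icam1 (1.58-fold). Of 20 antigen presentation genes Tap1 (1.69-fold) and Psmb9 (1.72-fold) rose (camera adjusted p = 0.0293, adjusted p = 0.526 with an estimated correlation). Adjusted over the list alone 3 passed, 2 higher and 1 lower. In the acute phase list Saa3 rose 4.45-fold (adjusted p = 0.00887) and Crp fell 1.35-fold among 25 (2 adjusted over the list alone; camera adjusted p = 0.086, adjusted p = 0.718 with an estimated correlation). Its median was -0.22, its mean 0.04 and the direction of its test downward. Calls were lost for Icam1 (0.54 to 0.76) without EcSTH 1, 2 or 4 or GFP 1, 2 or 4, Tap1 (0.61 to 0.87) without any EcSTH sample or GFP 1 or 2, and Psmb9 (0.61 to 0.93) without EcSTH 1, 3 or 4 or any GFP sample. Calls were also lost for Crp (-0.49 to -0.35) without EcSTH 1, 2 or 4. The number of risen interferon-stimulated genes was 7, 8, 8 and 6 without EcSTH samples 1 to 4 in turn and 4, 4, 13 and 8 without GFP samples 1 to 4. The antigen presentation list missed the threshold without EcSTH 4 (adjusted p = 0.139) or GFP 1 (0.0573), and the acute phase list passed it without GFP 1 (0.00613) or GFP 3 (0.0388).

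Markers of other cell types showed few calls. Of 16 Kupffer cell and macrophage genes Clec4f fell and Mpeg1 rose 1.51-fold (3 adjusted over the list alone; camera adjusted p = 0.169, adjusted p = 0.631 with an estimated correlation). Clec4f, a marker of resident Kupffer cells, read 1068, 929, 620 and 178 in GFP samples 1 to 4 and 127 ± 34.1 in EcSTH (4.67-fold lower, adjusted p = 0.0315). Vsig4, another resident marker, read 208, 193, 135 and 29.1 in GFP and 32.6 ± 3.39 in EcSTH (adjusted p = 0.0766), and Timd4 read 62.0, 58.5, 52.6 and 4.01 in GFP and 12.9 ± 5.34 in EcSTH (adjusted p = 0.359). Folr2, a macrophage folate receptor gene, fell 2.38-fold, and the lectin-like gene Clec2h fell 2.85-fold. Of 16 endothelial genes Stab1 (1.31-fold) and Clec4g (1.28-fold) fell (4 adjusted over the list alone; camera adjusted p = 3.85e-06; adjusted p = 0.325 with an estimated correlation). Limma called none of the tested T cell (7), NK cell (6), B cell (4), neutrophil (5) or stellate cell (16) genes alone. At an unadjusted p under 0.05 there were 1, 2, 1, 0 and 3, with edgeR 0, 0, 0, 0 and 0 and with DESeq2 0, 1, 0, 0 and 2, in that order. The stellate list lay lower (mean log2 -0.19, camera adjusted p = 0.0244; adjusted p = 0.432 with an estimated correlation), and the others gave camera adjusted p = 0.699 for T cells, 0.0568 for NK cells, 0.364 for B cells and 0.768 for neutrophils. These 4 had adjusted p = 0.738, 0.325, 0.687 and 0.796 with an estimated correlation. T cell genes had a median of 0.28, a mean just under 0 and an upward test, and neutrophil genes -0.04, 0.04 and a downward test. Adjusted over the list alone, 1 NK gene passed and none of the other 4 lists' genes did. Tm4sf4 of the bile duct list fell 1.28-fold among 10 (1 adjusted over the list alone; camera adjusted p = 0.0904, adjusted p = 0.35 with an estimated correlation), and the globin gene Hba-a2 fell 1.44-fold among 10 erythroid and platelet genes (2 adjusted over the list alone; camera adjusted p = 0.0414; adjusted p = 0.511 with an estimated correlation). Calls were lost, with the range of log2 over the fits without a sample in brackets, for Clec4f (-2.78 to -1.93), Folr2 (-1.51 to -1.06) and Tm4sf4 (-0.40 to -0.31) without any EcSTH sample or GFP 1, 2 or 3, for Mpeg1 (0.49 to 0.68) without EcSTH 1, 2 or 4 or any GFP sample, and for Clec2h (-1.81 to -1.33) without EcSTH 1, 2 or 4 or GFP 1. Calls were also lost for Stab1 (-0.44 to -0.33) without any EcSTH sample or GFP 1 or 2, and for Clec4g (-0.42 to -0.30) and Hba-a2 (-0.65 to -0.43) without EcSTH 1, 2 or 4 or GFP 1, 2 or 3. Without a sample, lists that lost the threshold were the stellate list without EcSTH 3 (adjusted p = 0.201) or GFP 3 (0.128) and the erythroid list without EcSTH 1 (0.135), GFP 1 (0.0547), GFP 2 (0.0836) or GFP 3 (0.0563). Lists that gained it were the NK list without EcSTH 1 (0.0363), EcSTH 2 (0.0439), GFP 1 (0.0249) or GFP 2 (0.0413), and the Kupffer cell (0.00332) and bile duct (0.0392) lists without GFP 4.

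Pancreatic transcripts were in excess in 3 of the 4 EcSTH libraries, mostly in sample 1. Reads of the acinar genes of the fixed list numbered 8362, 709, 213 and 44 in EcSTH samples 1 to 4 and 41, 38, 42 and 49 in GFP. EcSTH sample 4 was thus at the GFP level. Cela3b, a pancreatic elastase gene, was listed at 298, 20.3, 10.9 and 5.06 in EcSTH and at 0 in all 4 GFP libraries, at least 26.8-fold higher taking 3 reads per GFP library as the floor (adjusted p = 0.0383). Without EcSTH sample 1, which carries most of that mean, the same floor gives at least 3.87-fold. It was tested in 7 of the 8 fits, since its mean without EcSTH sample 1 was under 10. Its call was lost (log2 4.70 to 5.40) without EcSTH 2 or 4 or any GFP sample. It was the only 1 of 11 adipocyte and pancreas genes to pass (7 adjusted over the list alone; camera adjusted p = 0.000518; adjusted p = 0.428 with an estimated correlation), and the list missed the threshold without EcSTH 1 (adjusted p = 0.229). The amylase gene Amy2a5 read 2667, 255, 0 and 0.844 in EcSTH and 0 in GFP (adjusted p = 0.201), and the lipase gene Pnlip 699, 41.6, 27.2 and 0 in EcSTH and 0 in GFP (adjusted p = 0.0984).

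**Figure D2:**
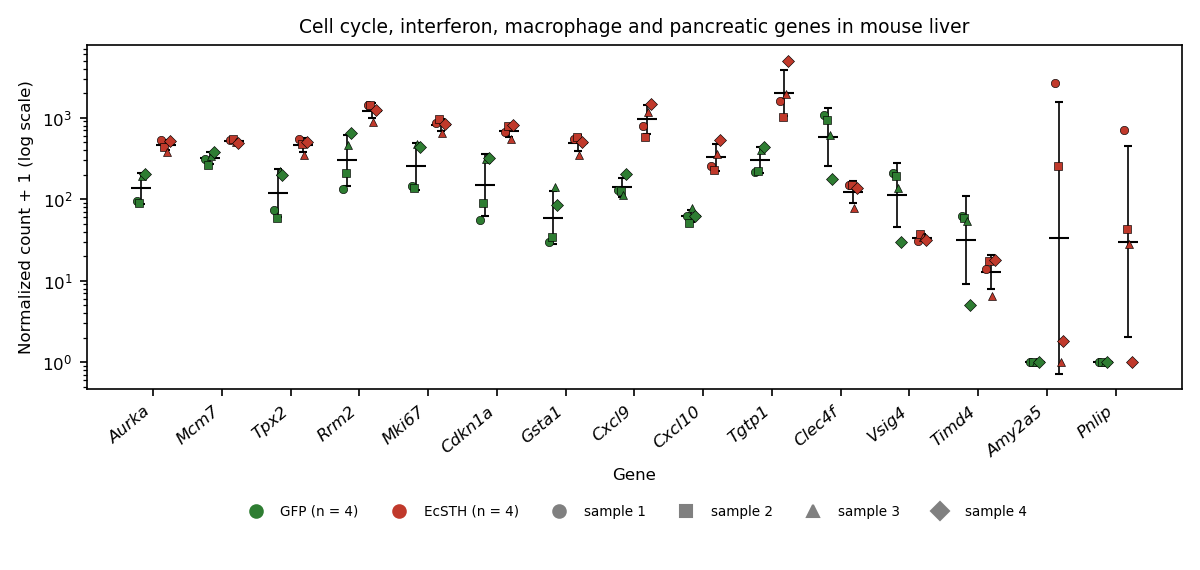
Normalized counts plus 1 (log axis) of 15 cell cycle, detoxification, interferon, macrophage and pancreatic genes in the 8 liver samples (green GFP, red EcSTH, marker shape by sample number, black bars mean and SD of log2 values, n = 4 per group). GFP samples 1 and 2 are lowest for Mki67 and Cdkn1a, GFP sample 4 is lowest of its group for Clec4f, and EcSTH sample 1 is highest for Amy2a5 and Pnlip.

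Detoxification genes of the NRF2 pathway rose. Of 23 listed targets 6 rose and none fell (13 adjusted over the list alone; camera adjusted p = 6.22e-08; adjusted p = 0.321 with an estimated correlation). The glutathione transferase gene Gsta1 rose 8.24-fold (71.5 ± 52.3 to 495 ± 105, adjusted p = 0.0122) and held its call, with Pgd, in all 8 fits without a library. Its near copy Gsta2 overlapped between the groups (377 ± 84.2 to 439 ± 112, log2 0.21, SE 0.20, adjusted p = 0.578). GFP samples with less Gsta2 (319 and 294 against 425 and 470) also had less Gsta1 (28.5 and 33.3 against 140 and 84.2). The sum of both rose 2.11-fold (448 ± 129 to 934 ± 205, adjusted p = 0.0242). That call was lost (0.94 to 1.23) without EcSTH 1, 2 or 4 or GFP 1 or 2. Srxn1, the sulfiredoxin gene, rose 1.70-fold and Gstm1 1.59-fold. Of 14 heat shock genes Hspa1b (1.73-fold) and Hsp90aa1 (1.64-fold) rose (2 adjusted over the list alone; camera adjusted p = 0.0244; adjusted p = 0.331 with an estimated correlation). In the integrated stress response list Gdf15 and Fgf21 rose among 26 (2 adjusted over the list alone; camera adjusted p = 0.461, adjusted p = 0.631 with an estimated correlation), with a median of -0.05, a mean of 0.28 and an upward test. Limma called none of 20 unfolded protein response genes alone (6 at an unadjusted p under 0.05, 0 with edgeR and 1 with DESeq2; mean log2 -0.11, camera adjusted p = 0.0433; adjusted p = 0.526 with an estimated correlation). The hypoxia list had 2 falls, Ndrg1 (1.59-fold) and Pdk1 (1.25-fold), among 15 (3 adjusted over the list alone; camera adjusted p = 0.0955, adjusted p = 0.321 with an estimated correlation). The transferrin receptor gene Tfrc rose 1.89-fold among 18 iron and heme genes (1 adjusted over the list alone; camera adjusted p = 0.858, adjusted p = 0.871 with an estimated correlation). Of 12 immediate early genes limma called none (0 at an unadjusted p under 0.05, 0 with edgeR and 0 with DESeq2; camera adjusted p = 0.699, adjusted p = 0.718 with an estimated correlation), as for 26 ribosomal protein genes (0 at an unadjusted p under 0.05, 0 with edgeR and 0 with DESeq2; camera adjusted p = 0.918, adjusted p = 0.98 with an estimated correlation). Median, mean and test differed in sign for iron and heme genes (0.03, 0.02, downward) and ribosomal protein genes (-0.02, 0.01, downward). Not past the threshold in some fits were Srxn1 (0.67 to 0.88) without EcSTH 2 or 4 or GFP 2, Gstm1 (0.57 to 0.80) and Hsp90aa1 (0.59 to 0.83) without EcSTH 1, 2 or 4 or GFP 1, 2 or 4, and Ndrg1 (-0.74 to -0.61) without EcSTH 4. Calls were also lost for Pdk1 (-0.34 to -0.27) without EcSTH 1, 2 or 4 or GFP 1 or 2, for Tfrc (0.82 to 1.05) without EcSTH 1 or 4 or GFP 1 or 2, and for Fgf21 (1.59 to 2.24) without EcSTH 2, 3 or 4 or GFP 1 or 2. The number of risen NRF2 targets was 3, 2, 9 and 2 without EcSTH samples 1 to 4 in turn and 3, 2, 9 and 4 without GFP samples 1 to 4. The unfolded protein response list missed the threshold without EcSTH 2 (adjusted p = 0.0528), EcSTH 3 (0.196), GFP 2 (0.184) or GFP 3 (0.0815), and the heat shock list without GFP 1 (0.0790).

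Outside the lists, the largest rises included the phosphate transporter gene Slc34a2 (10.2-fold, 14.9 ± 9.65 to 163 ± 111), the calcium pump gene Atp2b2 (7.61-fold, 53.8 ± 27.2 to 415 ± 213), Ttc25 (8.13-fold) and Radil (12.2-fold). The largest falls included the kinase genes Sgk2 (2.27-fold, 1562 ± 119 to 694 ± 132, adjusted p = 0.00496) and Map2k6 (2.70-fold), and the adaptor gene Sh2d4a (2.64-fold). All but Radil held their calls in every fit without a library. The call was lost for Radil (3.06 to 4.15) without EcSTH 1, 2 or 4 or GFP 2.

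**Figure D3:**
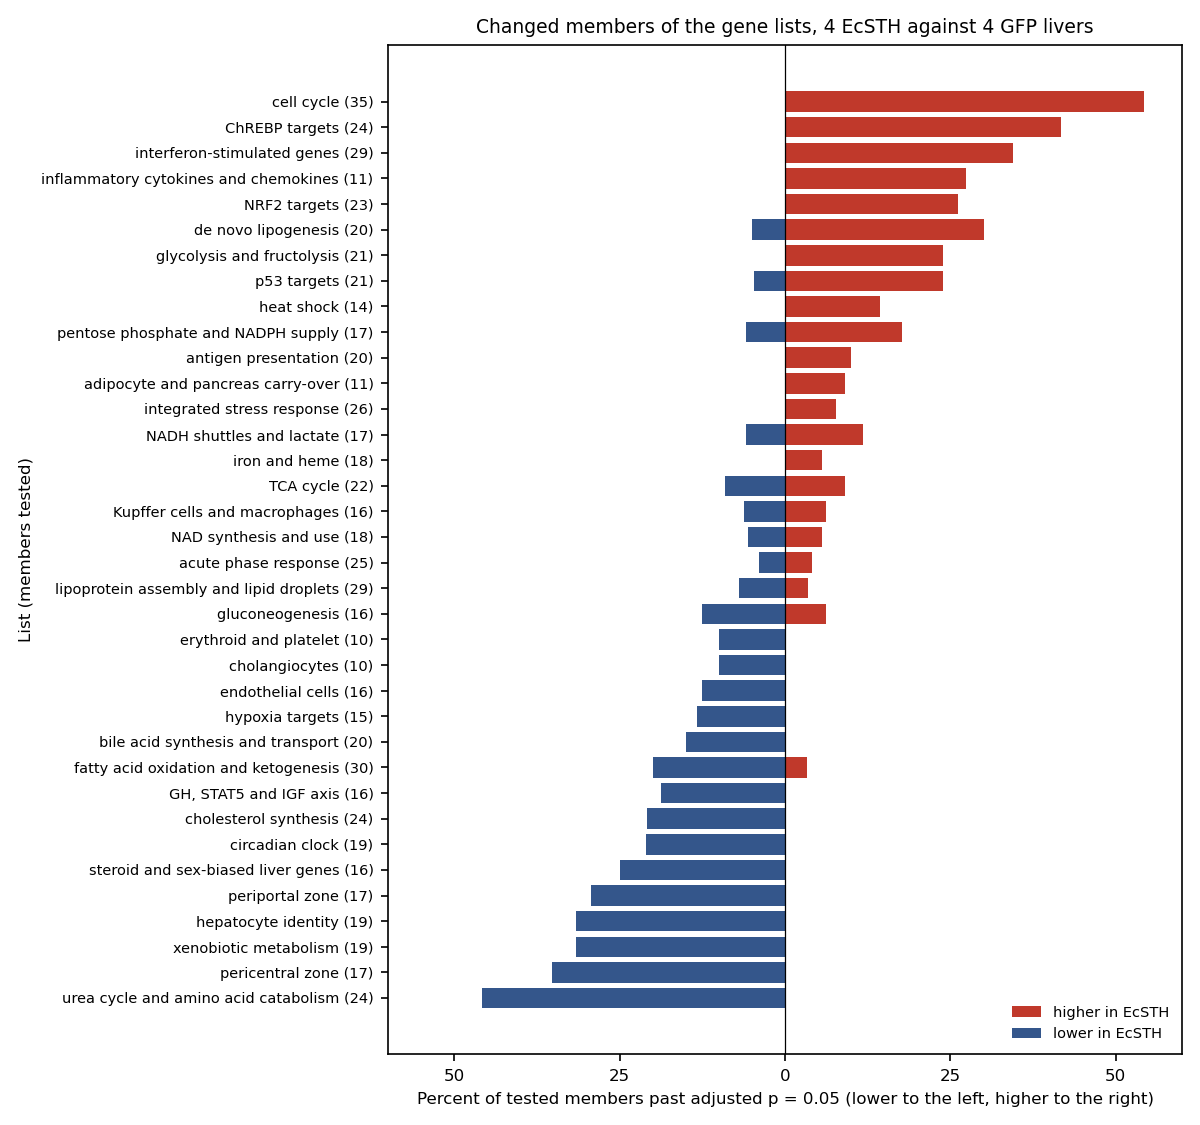
Percent of the tested members of each gene list that rose (red, right) or fell (blue, left) in EcSTH against GFP livers (n = 4 per group, limma), with the number tested in brackets and lists with no changed member left out. Cell cycle and ChREBP target lists lead the rises with 19 of 35 and 10 of 24 genes, and the urea cycle and amino acid list leads the falls with 11 of 24.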

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

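The values below stand apart from the other 3 samples of their group by Dixon's gap ratio on the log2 scale, 15 of 349 groups of 4 examined, where chance alone marks about 1 in 20. No explanation was weighed for them. In EcSTH sample 3, Clec4f was low at 76.0 (others 138 to 147), Clec2h high at 263 (others 102 to 120.0), Clec4g high at 852 (others 745 to 759) and the Kupffer cell and macrophage list low at -0.40 (others -0.14 to -0.09). In EcSTH sample 2, Dak was high at 20248 (others 15156 to 15232), as was Pdhb at 4311 (others 3436 to 3562), and Pnpla2 was low at 1723 (others 2023 to 2081). In EcSTH sample 1, Cyp2c50 was high at 7701 (others 6627 to 6734). In GFP sample 1, Cyp4a31 was high at 457 (others 277 to 287), as was the steroid and sex-biased list at 0.27 (others 0.00 to 0.01). In GFP sample 2, Sdhc was high at 3334 (others 3127 to 3144), Slc27a5 at 24070 (others 17723 to 18301) and the pericentral list at 0.46 (others 0.12 to 0.14). In GFP sample 4, Espl1 was at 71.1 where the others were listed at 0, and Timd4 was low at 4.01 (others 52.6 to 62.0). All values are normalized counts, except the list levels, which are mean log2 levels centred over the 8 samples.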

How the results depend on the processing

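Tests with the 3 covariates (mitochondrial mRNA share, cell cycle level, acinar marker level) were chosen after the data were seen. The count of 852 genes stayed within 1.5 times under every change of pseudocount, filter, scaling, weights, robust fit and edgeR (664 to 1058) and with the mitochondrial covariate (1155), and genes called both here and there had the same direction in each. Median-ratio rescaling moved nothing, so it tests nothing. The count was 249 without the variance trend, 1507 with DESeq2, 34 when a change of over 1.2-fold was asked for, 76 with the acinar covariate and 0 with the cell cycle covariate (limma; 871 at an unadjusted p under 0.05; 835 of the 852 in the same direction). That covariate follows the groups, which widens each error; the cause of the other shifts was not tested. Leaving out each library gave 193 to 909 genes, from fewer samples; without EcSTH sample 1, 43.1% of calls were rises, against 53.2%. Same-numbered samples shared little deviation over all tested genes (correlations of -0.02, -0.01, 0.06 and 0.08), which does not exclude pairing in a part of the genes. The replicate block, which uses up degrees of freedom, gave 160 genes and 28 lists. Of the 46 lists, 26 passed at the preset correlation, 21 to 29 under other settings of camera, 23 to 28 without a library, 19 and 36 with fry's directional and mixed tests, and 0 with an estimated correlation (26 at the preset one). The direction of the test turned only for results not past the threshold, except the unfolded protein response list; the mean of the bile acid list, past the threshold at -0.028, also rose above 0 (0.077 with quantile normalization, 0.011 without GFP sample 1). The cause was not tested. With quantile normalization, log2 values were 0.066 for Cpt1a, 0.087 for Mlxipl and 0.0049 for Txnip, and list means 0.10 for ribosomal proteins (adjusted p = 0.0104, then past the threshold), 0.088 for iron, 0.12 for mitochondrial mRNAs, 0.051 for the TCA cycle, 0.054 for NADH shuttles and -0.025 for the unfolded protein response. With the cell cycle covariate they were 0.052 for Cpt1a, -0.43 for G6pc, 0.082 for Mlxipl, 0.34 for Txnip and 0.44 for Timd4, and with the acinar covariate 0.021 for Mlxipl, 0.12 for Txnip and -0.15 for Scd1. Array weights gave -0.017 for Scd1. Without a filter, neutrophils had 0.15 and ribosomal proteins 0.10. Tests turned for lipoprotein genes (0.065 with DESeq2, 0.064 with edgeR, 0.078 with fry), ribosomal proteins (0.013 with DESeq2, 0.012 with edgeR), iron (0.016 with DESeq2) and NADPH supply (0.14 with the replicate block). Without a library, ranges were -0.27 to 0.089 for Txnip, -0.17 to 0.17 for Scd1, -0.13 to 0.031 for Mlxipl, -0.32 to 0.15 for mitochondrial mRNAs, -0.076 to 0.17 for ribosomal proteins, 0.11 to 0.17 for NADPH supply, 0.0054 to 0.036 for iron and 0.047 to 0.10 for lipoprotein genes. At these depths limma recovered 56.7% of simulated 2-fold changes.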

Other observations

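Tests of the groups' chance separation, of pancreatic carry-over and spill, and of ChREBP scaling and the size of the ChREBP change with the covariate were set before their results were seen; the tests of an acinar response in every liver, of depth, of muscle reads against spill, of weakly reacting GFP livers (1 or both left out) and of the covariate's interval, with and without Pnpla3 and Fgf21, were chosen only after.

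Skeletal muscle transcripts, 12 genes chosen after the data were seen, were also uneven between livers and did not follow the groups. They made 246, 4.69, 0.358 and 296 reads per M in EcSTH samples 1 to 4 and 201.0, 188, 34.6 and 342 in GFP samples 1 to 4. The acute phase gene Saa1, also chosen after its values were seen, read 2346, 554, 981 and 2538 in EcSTH and 464, 2079, 323 and 715 in GFP.

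The grouping itself was compared with all 35 ways to divide the 8 samples into 4 and 4. The real division gave 852 genes, and the highest of the others 3, so 1 of the 35 divisions gave as many. For lists the real division gave 26 and the highest of the others 22 (median 12), again 1 of 35. The real division ranked first for both counts, and 1 of 35 is the smallest share this test can give. Its lead was wide for genes (852 against 3) and narrow for lists (26 against 22). Since other divisions also moved many lists, the list count alone does not exclude chance.

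Pancreatic enzyme transcripts set EcSTH sample 1 apart. A list of 20 acinar genes, separate from the pancreatic genes of the fixed list, made 117, 9.37, 3.34 and 0.703 reads per M in EcSTH samples 1 to 4 and 0.350 to 0.695 in GFP. A response to EcSTH in every liver is argued against, since the lowest EcSTH library was 1.01 times the highest GFP library. Spill of reads from EcSTH sample 1 into samples 2 and 3 is argued against as their main source: it would have carried 337 and 101 muscle reads along with the acinar reads, and 84 and 6 were found (ratios of 0.250 and 0.0594), while the fit of the acinar reads to a shared profile (chi-square over degrees of freedom of 3.58 at the most) did not decide. Carry-over of pancreatic tissue or RNA may be the source, and 60% of the acinar genes (12 of 20) had at least 5 reads in EcSTH sample 1 and at most 1 in each GFP sample, between the 75% it would need and the 25% that would exclude it, so it stays open beside a response in some livers only, which was not tested.

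Cell cycle genes were higher in EcSTH livers and uneven in GFP livers. Sequencing depth is argued against, since the list's level had a correlation of -0.127 with total reads after group means were taken out. A weaker reaction of some GFP livers to the virus may add to the difference, which was 1.52 in log2 with all samples and 0.776 without both low GFP samples, 1 and 2, beside an SD of 0.859 among GFP samples. Leaving out only 1 of the 2 gave 1.25 at the least, but the other low sample stayed in, so that value weighs little. As 0.776 lies between the 0.5 and the 1 set as bounds, such a reaction and a response to EcSTH cannot be told apart.

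ChREBP targets did not follow the unevenness of the cell cycle genes in GFP livers, where the list level was -0.47, -0.20, -0.39 and -0.33. Scaling is argued against, since 0.9 of the 10 called targets stayed past the threshold under TMM-type or quantile scaling, whichever was lower. The reaction that raises cell cycle genes was weighed as the whole cause, with the cell cycle level as a covariate. The called targets' mean change was then 1.35, with a 95% lower bound of 0.632. These targets were picked for their rise in the same samples, so a bound above 0 weighs little. With the covariate 8 of the 10 shrank, and Pnpla3 (2.32 to 3.69) and Fgf21 (1.95 to 2.38) grew. Without this pair the called targets' mean change was 0.92 (lower bound 0.264). Over all 24 listed targets it was 0.74 (0.16 to 1.33), and over the 22 without the pair 0.53, where the interval took in 0 (-0.03 to 1.09). As the listed targets' interval was above 0 only with the pair, the reaction as the whole cause is not excluded. A part of the rise may come from that reaction, since the median change of the called targets with the covariate was 0.855 times that without (0.98 against 1.14). That ratio is above the bound of 0.75 by less than its jackknife SE over the libraries of 0.153. The mean change of the called targets did not shrink. Within groups, the slope of their mean level on the cell cycle level was -0.03 (SE 0.15). The reaction thus stays open beside a response to EcSTH. Such a response need not run through ChREBP, whose activity was not measured. Mlxipl and Txnip did not pass the threshold, and several called targets are also in the de novo lipogenesis list. Other regulators were not tested.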
